A study of Drosophila melanogaster with 4 samples.

How the data were processed

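Formaldehyde-crosslinked chromatin of larvae of the third instar was sonicated and precipitated with the H3K79me2 antibody, per the labels' protocols. Sequencing of the 2 ChIP and 2 input samples was followed by alignment with Bowtie 0.12.7, per the submitters' processing notes. The deposited lists give each cluster as a first and last base, counted from 1, on FlyBase release 5, per the file headers. The authors also gave each cluster a signed score, which was above 0 in all clusters named enriched and below 0 in all clusters named depleted. The scale and log base of the score, the cluster caller, its threshold and the use made of the inputs are not given in the sources used here. A list was deposited for each ChIP replicate and for the whole series, and how the replicates were combined in the latter is not given in the sources used here. The minimum cluster width was 1302 bp in replicate 1, 1301 bp in replicate 2 and 1001 bp in the whole-series list. All widths of the whole-series list were odd numbers, against 51.1% and 51.3% in the replicates, so that list was made on another grid of positions. Whether the caller saw more reads in one replicate is unknown, since no list holds counts, and depth could change both the number and the width of calls.

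Enriched clusters entered all comparisons, and depleted clusters were kept apart. Covered bases were the union of a list's clusters on an arm, and arm lengths came from the file headers. Replicates were compared by the Jaccard index of covered bases and by the share of clusters with at least 1 base in the other list. Wilson 95% intervals cover counting error only and treat clusters as independent. Chance overlap was drawn from 1000 circular shifts of the replicate 2 clusters along each arm, which keep widths and spacing, and its p is one-sided. The covered share per arm was given per replicate and as a mean with SD, and X and chromosome 4 were set over the mean of the 4 autosome arms. Cluster widths on X and the autosome arms were compared by a two-sided permutation test of the medians with 100000 resamples, adjusted over 3 lists by Benjamini-Hochberg. Scores were divided into quartiles within their own list. The whole-series list, which carries no replicate error of its own, was compared with each replicate.

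These choices and their alternatives were fixed before the data were examined, except the ratio for chromosome 4, since the plan named a ratio for X only. The alternatives were the clusters at or above the median score or width of their list, clusters under 1 kb apart joined first, overlap of at least 50% of the cluster, and 50% reciprocal overlap with a single cluster. Further ones were lists of equal size, random placement in place of shifts, shares of all covered bases, each replicate or autosome arm left out, and the whole-series list. An alternative without the 1 Mb next to the centromere was added after the data were seen, as was an exact test of the order of the major arms in both replicates. Regions were named by a rule fixed beforehand for the case of no annotation of the same release. It took the 10 widest and 10 highest-scored clusters of the whole-series list, the widest of each arm, the 5 widest clusters of each replicate with no base in the other, and the longest cluster-free stretch of each major arm. Regions named outside it are said to be so. The gene table used with this series is of Release 6, so cluster positions were not matched to genes, and the planned comparisons of genes, gene lists, positions within genes and genomic features were not run.

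The overlap and width steps were tested on simulated data before use. With 79.3% of the 6126 replicate 1 clusters kept in place in a copy and the rest moved at random, 81.4% were found overlapped. In 20 runs with clusters placed at random, 2 gave p under 0.05. For the width step, the replicate 1 widths of X and the autosome arms were first shuffled together. Widening a set of the size of X by 1.2-fold was then detected (permutation p = 0.000999, the smallest its resamples can give). The shuffled widths left unchanged gave a permutation p of 0.388. Smaller differences in width were not simulated, so the power to find them is unknown. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.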

Results

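Dimethylation of lysine 79 of histone H3 (H3K79me2) was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Drosophila melanogaster larvae of the third instar, the last larval stage before pupation. The larvae were of the wild-type Oregon-R strain. In flies the mark is placed by grappa, the homologue of the methyltransferase Dot1, and is known from the bodies of transcribed genes. The 4 samples were 2 ChIP replicates, made with an Abcam antibody against H3K79me2, and 2 input samples of chromatin DNA taken without immunoprecipitation. A list of enriched clusters was analysed for each ChIP replicate, together with a list for the whole series. Values of the input samples were not analysed here, so no background level stands beside the cluster values. The lists hold positions and a score per cluster but no read counts, and the depth behind each cluster is therefore unknown. The score is the authors' own, its scale is not given in the sources used here, and it was used only to describe and rank clusters within a list. All positions are on FlyBase release 5, and no gene annotation of that release was used here.

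H3K79me2 clusters covered between 23.5% and 29.4% of each major chromosome arm, as means of the replicates, and under 1% of the heterochromatic scaffolds together. Replicate 1 held 6126 enriched clusters over 32.3 Mb and replicate 2 held 4839 over 30.4 Mb, which was 27.0% and 25.4% of arms X, 2L, 2R, 3L and 3R. Arm 2R was covered most, at 29.4% ± 1.78 (SD, n = 2), and arm 2L least of the major arms, at 23.5% ± 0.706 (SD, n = 2). Arm 3R stood at 27.2% ± 1.38, arm 3L at 25.8% ± 0.860 and arm X at 25.3% ± 0.870 (each SD, n = 2). The order of the 5 arms was the same in both replicates (one-sided exact test over the 120 orders within replicates, p = 0.00833, the smallest it can give, chosen after the values were seen), and replicate 1 was the higher on each of them. The whole-series list held 5971 clusters over 35.3 Mb, 29.5% of the major arms, more than either replicate. Within a replicate, 2R exceeded 2L by 6.67 percentage points in replicate 1 and 5.15 in replicate 2. With 2 replicates no exact test of a single pair of arms can reach 0.05, the smallest two-sided permutation p being 0.5 for differences within a replicate and 0.333 for arms taken as separate samples.

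**Figure D1:**
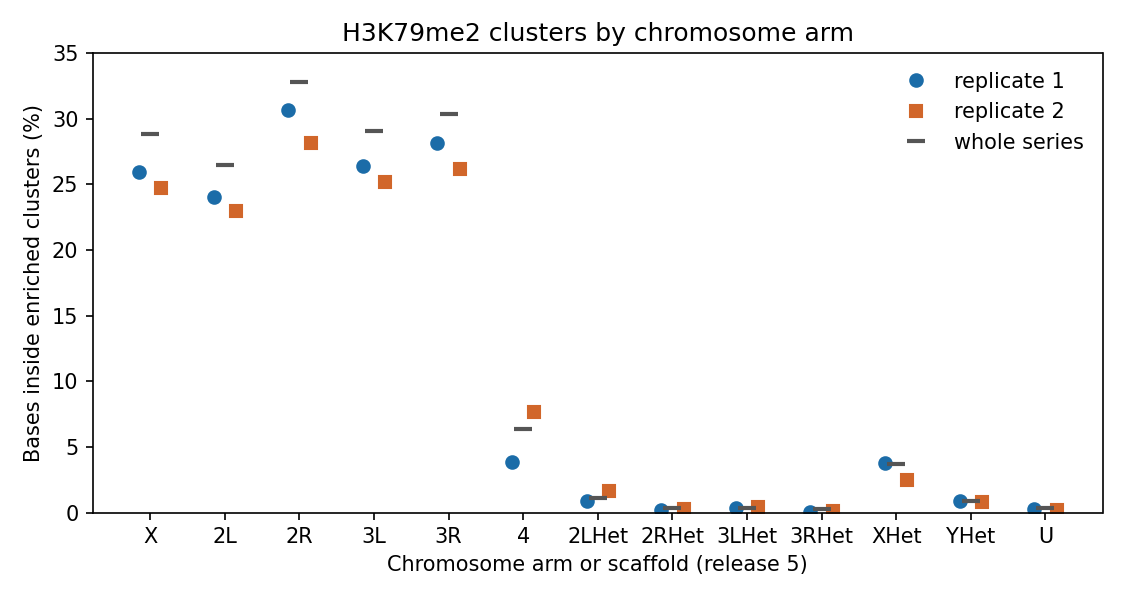
Share of bases inside enriched H3K79me2 clusters (%) on each chromosome arm or scaffold of release 5, with circles for replicate 1, squares for replicate 2 and dashes for the whole-series list. The means of the major arms lie between 23.5% and 29.4%, chromosome 4 at 3.82% and 7.69%, and the scaffolds named Het and U below 4%.

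Chromosome 4 and the heterochromatic scaffolds were covered less than any whole major arm in both replicates. Chromosome 4, a small chromosome known for its mixture of genes and repeats, was covered at 3.82% in replicate 1 and 7.69% in replicate 2, or 5.76% ± 2.73 (SD, n = 2). Its share relative to the mean of arms 2L, 2R, 3L and 3R was 0.140 in replicate 1 and 0.300 in replicate 2, below all of the major arms in each. The mean ratio of 0.220 became 0.0856 with only the clusters at or above the median width of their list, and 0.0123 as a share of all covered bases, which includes the length of the arm. Chromosome 4 is 1.35 Mb long, and of 86 windows of that length on the major arms, 4 were covered no more than it, as means of the replicates. The 6 heterochromatic scaffolds together, 9.28 Mb of assembled sequence next to the centromeres and on Y, were covered at 0.330% and 0.418%. The unplaced sequence U, 10.0 Mb long, was covered at 0.252% and 0.224%. The highest scaffold was XHet, with 3.79% in replicate 1 and 2.46% in replicate 2, from 3 and 2 clusters. All these shares are of full lengths, with assembly gaps and sequence where reads cannot be placed counted as uncovered. Low cluster coverage here therefore need not mean absence of the mark.

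The replicates differed from each other on chromosome 4 more than on any major arm. Replicate 1 held 24 clusters over 51.7 kb there and replicate 2 held 35 over 104 kb, and the Jaccard index of their covered bases was 0.376. Of the replicate 1 clusters on chromosome 4, 19 had a base in replicate 2, and of the replicate 2 clusters 17 had a base in replicate 1. The widest replicate 2 cluster anywhere with no base in replicate 1 was on this chromosome, from 89651 to 94739. Within their own lists, the clusters of chromosome 4 had a median score above 19.5% of replicate 1 clusters and above 51.4% of replicate 2 clusters. The widest cluster of the chromosome in the whole-series list, from 71366 to 76396, was covered over 75.2% of its length in replicate 1 and over 100% in replicate 2.

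**Figure D2:**
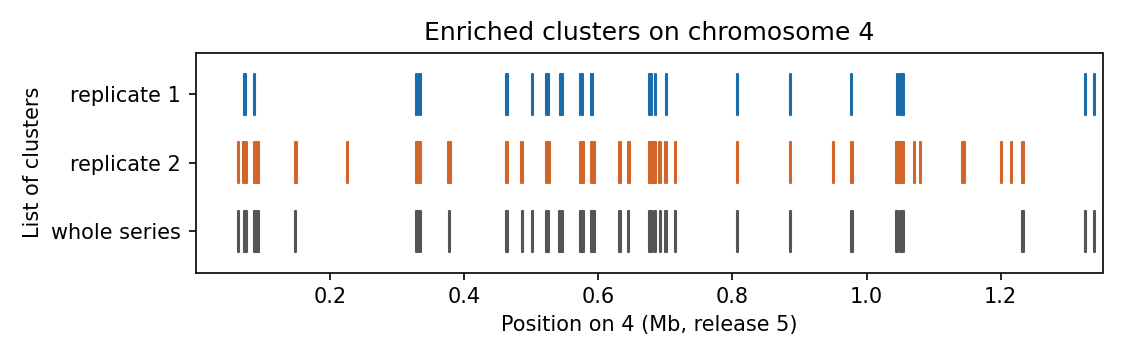
Positions of enriched clusters along chromosome 4 (Mb, release 5) in replicate 1 (24 clusters), replicate 2 (35 clusters) and the whole-series list (35 clusters). Each bar is a cluster drawn to scale along the position axis apart from a thin outline, and 18 of the replicate 2 clusters have no base in replicate 1.

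The X chromosome, which is present in a single copy in males and is dosage compensated, was covered within the range of the autosome arms. Its covered share relative to the mean of 2L, 2R, 3L and 3R was 0.951 in replicate 1 and 0.965 in replicate 2, a mean of 0.958 ± 0.00981 (SD, n = 2). Arm 2L was covered less than X in both replicates, while 2R, 3L and 3R were covered more. The closest was 3L, which exceeded X by 0.468 percentage points in replicate 1 and 0.482 in replicate 2. The larvae were not separated by sex in the labels. In score, X stood above the range of the autosome arms in each list, and no test was made of it. Its median score was 0.946 in replicate 1, against 0.789 to 0.901 on the autosome arms. In replicate 2 it was 0.907 against 0.796 to 0.833, and in the whole-series list 0.711 against 0.591 to 0.670. No difference in width between clusters on X and on the autosome arms passed an adjusted p of 0.05 in the lists as deposited. The median width on X was 3572 bp against 3379 bp in replicate 1, a difference of 192.5 bp (two-sided permutation test over clusters, p = 0.109, adjusted p = 0.163). In replicate 2 it was 3951 bp against 3851 bp (permutation p = 0.506, adjusted p = 0.506), and in the whole-series list 3668 bp against 3379 bp (permutation p = 0.0434, adjusted p = 0.130). The adjustment was Benjamini-Hochberg over the 3 lists. These tests take clusters as units, and clusters are not replicates. With clusters under 1 kb apart joined first, the difference of 780 bp in the whole-series list had an adjusted permutation p of 0.0457, while replicate 1 gave 329 bp (adjusted permutation p = 0.267) and replicate 2 gave 50.5 bp (adjusted permutation p = 0.851).

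The widest H3K79me2 cluster of the whole-series list lay on 3L from 17945706 to 18034566. It ran for 88.9 kb, had the second highest score of the list at 2.45, and was covered over 97.9% ± 2.94 of its length in the replicates (SD, n = 2). Next in width were 3R from 14873688 to 14957530, at 83.8 kb, and 3L from 22320928 to 22401518, at 80.6 kb. They were followed by 2R from 14167310 to 14245284, 3R from 5739580 to 5814076 and 2R from 6923620 to 6995014, at 78.0, 74.5 and 71.4 kb. The last of the 10 widest were 3L from 507200 to 574994, 3R from 10241302 to 10307984, 3L from 8818806 to 8881978 and 3R from 10554644 to 10617346, the narrowest of them 62.7 kb. Over these 10 regions the covered share ran from 92.9% to 99.6% in replicate 1 and from 84.1% to 100% in replicate 2. Several were split into different numbers of clusters in the replicates. The region on 3R from 5739580 held 2 clusters of replicate 1 and 8 of replicate 2, while that on 3R from 10554644 held 6 of replicate 1 and 1 of replicate 2. The widest cluster of X, from 1462992 to 1523062, measured 60.1 kb, and that of 2L, from 7918412 to 7978026, measured 59.6 kb.

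**Figure D3:**
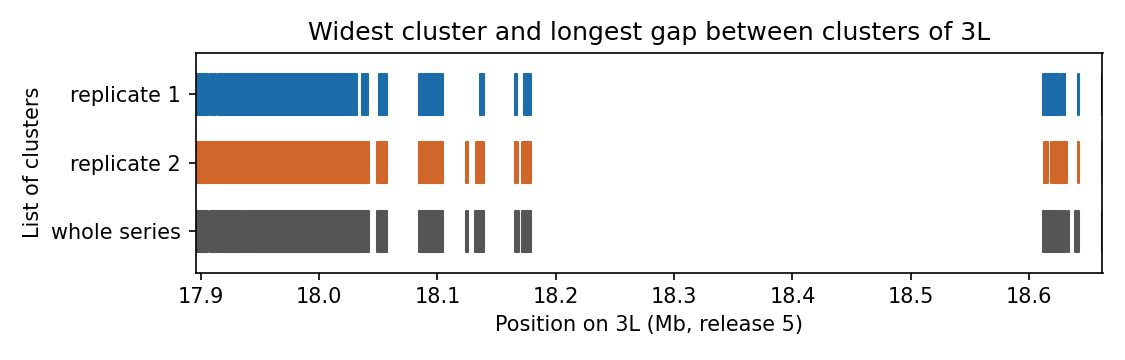
Enriched clusters on 3L (Mb, release 5) in replicate 1, replicate 2 and the whole-series list, around the widest cluster of the whole-series list (17945706 to 18034566) and the longest gap of the arm between clusters of that list (18179061 to 18612073). Bars are clusters to scale apart from a thin outline, which closes the narrowest gaps, and the gap shows as an empty block in all 3 rows.

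High scores were not confined to the very widest clusters. Among the 10 highest scores of the whole-series list, 3L from 17545450 to 17551616 scored 2.41 over 6.17 kb and 3R from 5630336 to 5635658 scored 2.38 over 5.32 kb. The others on the major arms were 2L from 5316462 to 5328858, X from 15212670 to 15220968, 3R from 5459688 to 5464056, 2R from 18685760 to 18690166, 2R from 16880632 to 16894460 and 2R from 1988356 to 2038596. Apart from the first-ranked cluster, all of these were covered over at least 93.1% of their length in each replicate. All of them were also wider than the median of the whole-series list, 3395 bp. The first-ranked, with a score of 2.61, was a cluster of 1993 bp on the heterochromatic scaffold 2RHet from 1013134 to 1015126, and neither replicate had a base of a cluster in it. Across clusters, width and score rose together, with a Spearman correlation of 0.81 in each of the 3 lists. The clusters are not independent replicates, and no test was made of it. Clusters ran from 1302 to 71818 bp in replicate 1, median 3385, and from 1301 to 104460 bp in replicate 2, median 3832. The widest 10% of the clusters held 34.0% of the summed width in replicate 1, 36.1% in replicate 2 and 37.7% in the whole-series list.

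Long stretches without any cluster lay on every arm. The longest in the whole-series list was the end of 3L next to the centromere, from 23143569 to 24543557 (1400 kb), which held no replicate 1 cluster and 5 replicate 2 clusters over 0.518% of its length. On 2L the longest ran from 16910961 to 17372889 (462 kb) and on X from 20532629 to 20900877 (368 kb). On 3R it ran from 23812109 to 24146277 (334 kb) and on 2R from 711791 to 977813 (266 kb). On chromosome 4, outside the rule for regions, it ran from 150079 to 328263 (178 kb). The stretches of X and 3R were empty in both replicates. The longest gap on 3L with clusters on both sides, from 18179061 to 18612073 (433 kb), was named apart from the rule for regions. On 2L a replicate 1 cluster reached into 0.0147% of the stretch and on 3L into 0.00439% of this gap, on 2R a replicate 2 cluster into 0.114%, and on chromosome 4 replicate 2 clusters into 1.25%.

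**Figure D4:**
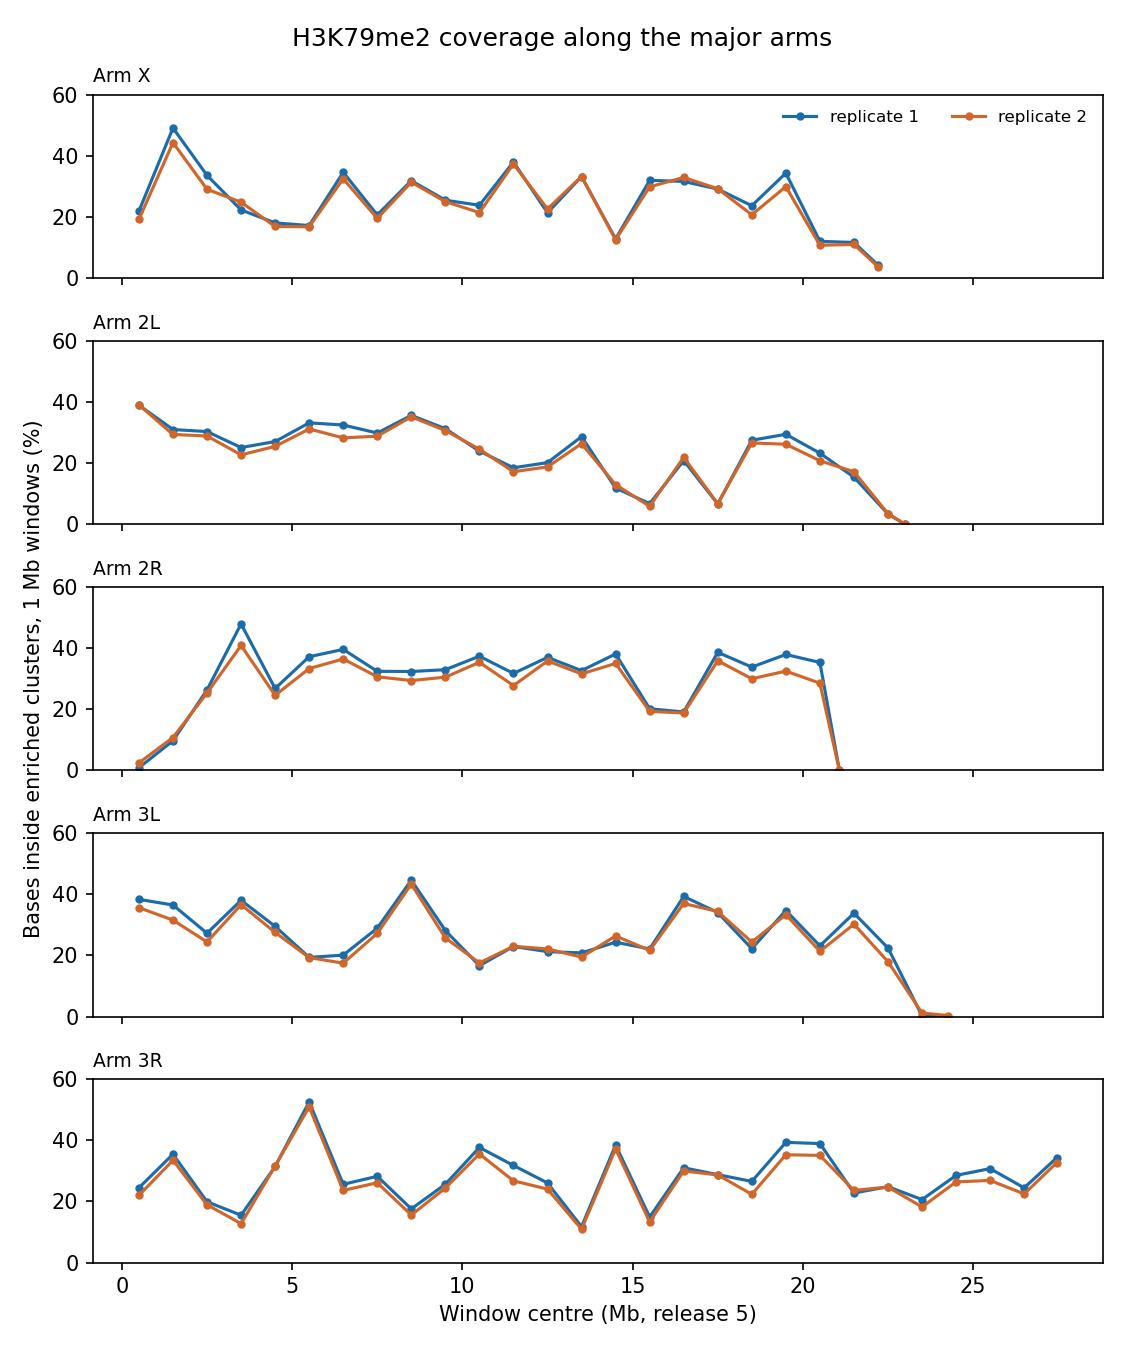
Share of bases inside enriched clusters (%) in consecutive windows of 1 Mb along arms X, 2L, 2R, 3L and 3R, plotted at the window centre (Mb, release 5), with circles and lines for each of the 2 replicates. The last window of an arm is shorter, and the highest window, 3R from 5000001 to 6000000, named after its values were seen, was covered at 52.6% and 51.0%.

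Along the major arms the replicates gave nearly the same profile. Over 117 full windows of 1 Mb their covered shares differed by a median of 1.69 percentage points and by at most 7.06, with replicate 1 the higher in 94 windows. The most covered window, named outside the rule for regions after its values were seen, was 3R from 5000001 to 6000000, at 52.6% in replicate 1 and 51.0% in replicate 2.

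Most of the bases inside clusters were common to both replicates. They shared 28.2 Mb, which was 87.5% of the covered bases of replicate 1 and 92.7% of those of replicate 2. The Jaccard index was 0.819, against a mean of 0.151 and a highest value of 0.211 when the replicate 2 clusters were shifted around each arm (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). By arm the index was 0.795 on X, 0.814 on 2L, 0.835 on 2R, 0.821 on 3L and 0.833 on 3R. Counted in clusters, 84.0% of replicate 1 clusters (5146 of 6126, Wilson 95% interval 83.1 to 84.9) and 94.8% of replicate 2 clusters (4589 of 4839, 94.2 to 95.4) had at least 1 base in the other list. The shifted lists gave means of 36.9% and 40.9%. Replicate 1 held 1.27 times as many clusters as replicate 2, over 1.06 times as many bases. Single replicate 2 clusters overlapped 2 or more replicate 1 clusters by at least 1 base in 709 cases, and the reverse held for 398 replicate 1 clusters.

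The clusters found in 1 replicate alone were narrow and low in score. The median width of the 980 replicate 1 clusters with no base in replicate 2 was 1654 bp, against 4071 bp for the 5146 that had one. For replicate 2 it was 1691 bp in 250 clusters against 4067 bp in 4589. By quartile of the authors' score within replicate 1, the overlapped share was 56.7% in the lowest (54.2 to 59.1), 80.1%, 99.3% and 100% in the highest (1532 of 1532, lower bound 99.7). For replicate 2 it was 84.1% in the lowest (82.0 to 86.1), 95.7%, 99.6% and 99.9%. Median width also rose from the lowest to the highest quartile, from 1729 to 7534 bp in replicate 1 and from 1796.5 to 9185 bp in replicate 2. Wider clusters meet a rule of 1 base more readily. No chance level was drawn per quartile, so score and width cannot be told apart here. When the overlap had to be 50% reciprocal with a single cluster, the lowest quartile of replicate 1 fell to 32.1%. The widest replicate 1 clusters with no base in replicate 2 were 2R from 9762184 to 9770167, 3L from 6723543 to 6730775 and 2L from 6380471 to 6386236, at 7.98, 7.23 and 5.77 kb. The next were 2L from 21224562 to 21230121 and 3L from 8583389 to 8588594. For replicate 2, after the cluster on chromosome 4, they were X from 3572182 to 3576786, X from 7586648 to 7591124, X from 15053045 to 15057190 and 2L from 10318263 to 10322255.

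**Figure D5:**
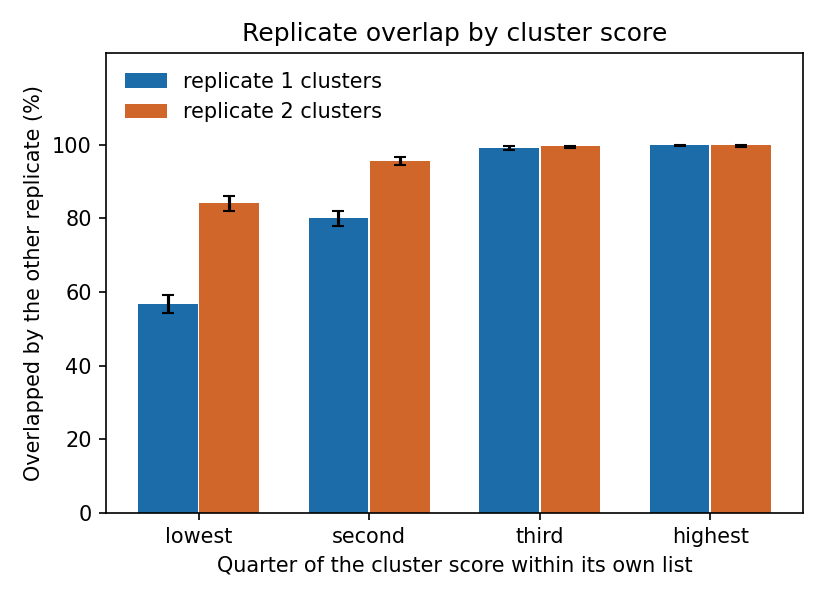
Share of clusters with at least 1 base in the other replicate (%), by quartile of the authors' score within each list, for replicate 1 and replicate 2. Error bars are Wilson 95% intervals, which cover counting error only, and the bars rise from 56.7% and 84.1% in the lowest quartile to 100% and 99.9% in the highest.

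Of the whole-series clusters, 71.0% (4239 of 5971, Wilson 95% interval 69.8 to 72.1) overlapped clusters of both replicates, and these held 91.8% of its width. A further 911 (15.3%) overlapped replicate 1 alone and 235 (3.94%) replicate 2 alone. The remaining 586 (9.81%, 9.09 to 10.6) overlapped neither, had a median width of 1229 bp and held 2.19% of the width. In the other direction, 99.2% of replicate 1 clusters and 99.1% of replicate 2 clusters had a base in the whole-series list. On YHet each list held 1 cluster, which in the whole-series list ran from 304644 to 307734 with a score of 1.39 and was covered over 97.7% and 90.8% of its length. The widest whole-series clusters of the other scaffolds were also found in both replicates. They were 2LHet from 167514 to 169538, 2RHet from 469992 to 472470, 3LHet from 594020 to 596638, 3RHet from 1934870 to 1936814, XHet from 59998 to 63086 and U from 6383934 to 6387402. The labels do not say whether the replicates came from separate collections of larvae, so the SDs given here measure only the difference between these samples. The p-values of the overlap and of the arm order concern only the agreement of these 2 replicates. Those of width compare clusters within a list.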

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

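The test against chance overlap was chosen after the overlap had been seen, and the test of score percentiles before its result was seen. Depleted clusters, those with a score below 0, entered none of the comparisons. They numbered 14 in replicate 1, 4 in replicate 2 and 15 in the whole-series list, each above the 3 that a count of 0 allows. The rate of false depleted calls is unknown, so that bound cannot show that they exceed it. No input level was analysed here to set beside them. Their widths ran from 1474 to 1844 bp, 1483 to 1722 bp and 1363 to 1789 bp. A single site was depleted in all 3 lists, on 3L from 19971730 to 19973390 in the whole-series list, a region named after its values were seen.

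Of the 18 depleted clusters of the replicates, 11 lay at least 50% inside an enriched cluster of the other replicate. Circular shifts placed a median of 4 and at most 11 of them inside (permutation p = 0.002), which argues against chance overlap. The enriched clusters that covered them had a median score percentile of 4.75 in their own list, with a range from 0.207 to 80.5, and 7 of the 11 were under 25. A candidate explanation is that many depleted clusters are marginal calls named by the sign of a score near 0, although the upper part of that range leaves some of them outside it. No biological explanation was tested, since the design holds a single stage and strain.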

How the results depend on the processing

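Among the alternatives, those without the 1 Mb next to the centromere and those for the order of the arms were chosen after seeing the data. The ratio for chromosome 4 was outside the plan. Of the values recomputed, 80 stayed on the same side of their threshold or within their spread, 40 moved beyond it, 1 passed a threshold and 0 reversed. Each of 2 replicates always lies within their SD of the mean, so values with a replicate left out could not count as moved. Those values are among the 80 and are no sign of stability. The Jaccard index ran from 0.765 to 0.819, each at the smallest permutation p. With 50% of the cluster covered, the overlapped share was 81.6% for replicate 1, 92.7% for replicate 2 and 67.8% for whole-series clusters in both, and the lowest score quartiles gave 52.9% and 80%. With 50% reciprocal overlap these were 61.2%, 77.4%, 59.9%, 32.1% and 62.0%, and the highest quartiles 88.1% and 90.3%. These rules admit fewer overlaps by construction, and the cause of the other shifts was not tested. With near clusters joined, replicate 2 gave 95.8%, whole-series clusters 75.8% and the lowest quartiles 52.6% and 86.8%, and the X width difference in the whole-series list became 780 bp (329 and 50.5 bp in the replicates, neither past the threshold). The upper part by score gave 83.4% for replicate 1, 96.0% for replicate 2, 75.3% for whole-series clusters and 0.987 for X over autosomes. Against the full other list, the third and highest score quartiles gave 99.3% and 100% in replicate 1. In replicate 2 they gave 99.6% and 99.9%. The other list was thus cut as well, so the overlap shares of the upper part by score also reflect lost partners. By width, the upper part gave 93.3% for replicate 2, 73.2% for whole-series clusters and 0.948 for X over autosomes, with 0.0856 for chromosome 4. As shares of all covered bases, which include arm length, the ratios were 0.890 for X and 0.0123 for chromosome 4. The whole-series list gave 0.972 for X. Leaving out each replicate gave 0.951 to 0.965 for X and 0.140 to 0.300 for chromosome 4, so a single replicate decides the size of the latter. All alternatives at the level of genes were not run, as no annotation of release 5 was used. Unknown depth keeps open whether weak clusters missing from a replicate were below detection. Between ChIP and input, no paired analysis was possible because the input samples, which share replicate numbers with the ChIP samples, have no values analysed here.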

Other observations

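In this part, all windows and stretches, and the tests on chromosome 4, were chosen after the values were seen, and the tests on whole-series clusters before their results were seen. Coverage by H3K79me2 clusters fell off within the arm sequence toward the centromere on 4 of the 5 major arms. Here the 1 Mb next to the centromere is the end of the arm sequence. It leaves out the heterochromatic scaffolds. Assembly gaps and sequence where reads cannot be placed were not set apart, so low coverage need not mean absence of the mark. In the 1 Mb next to the centromere it was 0% in replicate 1 and 0.365% in replicate 2 on 3L, against 27.5% and 26.3% on the rest of the arm. On 2R it was 0.894% and 2.48% against 32.1% and 29.4%, on 2L 3.40% and 3.52% against 24.9% and 23.9%, and on X 7.62% and 7.14% against 26.8% and 25.5%. The fall was small within the sequence of arm 3R, with 24.5% and 22.0% against 28.3% and 26.3%. The separate scaffold 3RHet was covered at 0.0774% in replicate 1 and 0.154% in replicate 2. The value of 3R therefore does not show that coverage is kept up to its centromere.

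Stretches of at least 100 kb without a cluster numbered 195 in replicate 1 and 214 in replicate 2 and took up 28.8% and 30.6% of the major arms. Most of their length was common to both, 33.3 Mb or 97.1% of the length in replicate 1 and 91.4% of that in replicate 2. Random placement of the replicate 1 clusters on the same arms gave a median of 6 such stretches and at most 13 in 1000 draws. That placement used the full arm, with assembly gaps and sequence where reads cannot be placed. It cannot show that the excess is particular to this mark. They took the largest share of an arm on X and 2L, at 33.4% and 33.2% in replicate 1 and 36.1% and 34.3% in replicate 2.

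Chromosome 4 had 2.01 times as many covered bases in replicate 2 as in replicate 1, a log2 ratio of 1.01, while all the major arms had fewer. Of 86 windows of its length on the major arms, 2 reached that ratio, with a median of -0.09, which argues against variation of any window of this length. Both lay next to centromeres, on 3L from 22981570 to 24333426 (log2 ratio 2.5628, mean coverage 0.495%) and on 2R from 1 to 1351857 (2.13%), but the 3 windows within a factor of 2 of the 5.76% of chromosome 4 had log2 ratios of 0.15, -0.07 and -0.15, too few to decide whether variation of thinly covered sequence may reach up to its coverage. As to a gain of replicate 2 over all repeat-rich sequence, 2LHet, 2RHet, 3LHet and 3RHet had 1.82, 1.77, 1.23 and 1.99 times as many covered bases in replicate 2 and the 6 heterochromatic scaffolds together were covered at 0.418% against 0.330%, while 2 of them, XHet and YHet, had 0.650 and 0.929 times as many and the unplaced sequence U 0.891 times, so with 1 to 5 clusters per scaffold and 12 and 11 on U it stays open. Read depth is unknown, and no biological explanation was tested, since the design holds a single stage and strain.

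Of the 586 whole-series clusters in neither replicate, 62.1% were narrower than the narrowest replicate cluster (1301 bp), against 8.59% of the whole list, so a smaller minimum width in that list may account for those 364. The share in the lowest score quartile was 63.1%. It was 66.3% for whole-series clusters in replicate 1 alone, 74.0% for those in replicate 2 alone and 8.14% for those in both. The 63.1% lay between the bounds set beforehand for weak sites that pass once the replicates are combined, and so does not decide that explanation. Neither property held for 61 of the 586. In the top score quartile were 3, named after their values were seen: 2RHet from 1013134 to 1015126, 2RHet from 32452 to 33470 and U from 9711686 to 9712812. The first has the highest score of the list, at 2.61, and its nearest replicate cluster lies 540656 bp away; no biological explanation was tested.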
